A study of Rattus norvegicus with 2 samples.

How the data were processed

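Total RNA of rat hippocampal neural stem cells was hybridised to 1-colour (Cy3) microarrays with probes for messenger RNAs and long non-coding RNAs. There were 2 arrays, 1 of cells kept under 2.4% sevoflurane and 1 of cells kept under 0% sevoflurane (the control). Per the labels, the cells came from Sprague-Dawley rats of postnatal day 3, were in passage 3, and spent 6 h under the gas and 24 h in an ordinary incubator at 5% CO2. The labels are not uniform on the time of harvest: some name only 6 h after exposure, so the age of the response is uncertain. The submitters' design text mentions more than 1 independent experiment, so an array may hold RNA of a single culture or of a pool, which the sources used here do not settle. Labelling used random priming along whole transcripts, per the labels' protocols.

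The scanner files hold spot intensity on a linear scale, written by Agilent Feature Extraction 11.0.1.1 per the file headers and the submitters' processing notes, with no scaling between arrays. Their processed signal is already corrected for background by that software. The design of the array refers to an older rat genome build (rn4), and the gene table used for names to another assembly (GRCr8), so no coordinates are given. A value table of 24529 rows was also deposited, of which 45 are control rows, and the method behind it is not given in the sources used here. Set against the logarithm of the scanner signals, its columns correlated at 0.991 (sevoflurane) and 0.993 (control) over 24431 probes, and both had a median of 5.61. The deposited values were therefore read as log2 intensities brought to nearly the same median and upper quartile (8.96 on both), since their differences correlated at 0.968 with those after quantile normalization here. Their lower quartiles differed, at 3.18 (sevoflurane) and 2.73 (control). Each column had a lowest value shared by many probes, 2.32 in 1145 probes for sevoflurane and 2.73 in 6163 probes for the control, so low values of that table are tied. The program, the centring and the reason for these lowest values remain unknown.

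Control spots were left out, as were spots flagged as non-uniform or as population outliers (521 of 42136 on the sevoflurane array and 580 on the control array). The processed signal was taken to log2, spots of a probe were averaged, and the 75th percentile over probes was subtracted from each array. Of 24684 probes, 55 had no usable spot on at least 1 array. A probe counted as measured when Feature Extraction called most of its usable spots well above background on both arrays. No spot was saturated. The precision is limited by the number of arrays: with 1 array per group there is no replicate check, no p-value can be given, and differences are described by size, with at least 2-fold (1 log2 unit) as the rule. Both arrays were scanned on different days, so scan day and group cannot be told apart. Spread between spots of a probe was taken over measured probes with at least 3 spots, and spread between probes of a gene over genes with at least 2 measured probes. Both are technical and leave out differences between cultures.

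RefSeq accessions in the files, without versions, were looked up in the gene table, which named 14274 of 15323 RefSeq mRNA probes and gave 13903 genes. A further 20 probes of the non-coding section were named in this way. The files do not state which probes are non-coding: that section (9319 probes) was recognised by the form of its probe names, and its members keep the names in the files. A gene was represented by its measured probe with the highest mean level. Older symbols in the gene lists were updated through unique synonyms.

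For each gene list with at least 5 measured members (31 of 32 lists), the median difference was placed among the medians of 10000 random lists of the same size, drawn from the 10036 measured genes and matched on mean level in 10 equal groups. A list was said to stand apart below percentile 2.5 or above percentile 97.5. Such a percentile is a description of these arrays and not a p-value. The lists, the size rule and the alternatives were fixed before the data were examined, except where the text says otherwise. The rule for named genes was also fixed then. It takes the 10 highest and the 10 lowest differences among genes of the brighter part of the measured genes whose probes all go the same way. To these it adds up to 4 members of each list with the highest absolute difference, the 3 strongest bounds in each direction, the 5 highest and 5 lowest non-coding probes of the brighter part, and a fixed set that includes Nes, Sox2, Hes1, Mki67, Pcna, Gfap, Tubb3, Dcx, Olig2, Bdnf, Cdkn1a and Aif1. Some genes that the rule takes are not reported here. Where a gene was well above background on 1 array only, its level there was set against the higher of its own signal on the dim array and the lowest signal among probes well above background there, which gives a lower bound for the fold. The E1A control sequences were treated in the same way.

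The alternatives were quantile normalization, the median over measured probes, an intensity-dependent correction (loess of the difference on the mean level, span 0.4), normexp background correction with an offset of 50, the deposited table, the brighter part of the measured probes, no filter, size rules of 1.5-fold and 3-fold, the mean over a gene's probes, and leaving out saturated probes. Normexp was run on median spot signals, because the mean spot signals named in the plan are not a column of the files. Its offset is added to every signal and shrinks log2 differences of dim probes by construction. Smaller differences of dim genes after normexp are therefore no separate check of them. Detection by a positive and significant signal, and a minimum signal taken from the E1A control sequences, were added after seeing the data.

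The scaling was tested on simulated data made from the real mean levels of 16047 measured probes with the real spot noise. With no trend on level, all scalings run recovered 100% of the 100 probes changed by 1.5 log2 units and called 0% of 15847 unchanged probes. With the trend on level that these arrays show, the 75th percentile scaling recovered 76% of them and called 27.3% of the unchanged probes. Median scaling recovered 78% and called 21.6%. The loess correction and quantile normalization each recovered 100% and called 0%. However, the trend put in was the loess fit itself, with spot noise only and few changed probes. The loess outcome was thus close to fixed beforehand. Neither it nor the quantile outcome shows that the scaling is right for these arrays. The list placement was tested on the real differences of 10036 genes: 4% of 200 random lists of 20 genes stood apart, against 94% of 50 lists shifted up and 100% of 50 lists shifted down by 1 log2 unit. The work used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.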

Results

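Gene expression was profiled in neural stem cells, the self-renewing precursors of neurons and glia, cultured from the hippocampus of newborn rats and treated with sevoflurane, an inhaled general anaesthetic, or with control gas. One microarray was available per group, so 1 sevoflurane array and 1 control array were compared, and no difference below has a replicate check. Whether an array stands for a single culture or for a pool of cultures is not given in the sources used here. Of 24629 usable probes, 16047 were well above background on both arrays, 4491 only on the sevoflurane array and 396 only on the control array. The upper quartile of the processed signal was 267 on the sevoflurane array and 476 on the control array, the lower quartile 15.1 and 3.32. Spots of a probe had a median SD of 0.088 log2 units on the sevoflurane array (4506 probes) and 0.068 on the control array (4491 probes). Differences are given as sevoflurane minus control in log2 units.

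The comparison asks which messenger RNAs and long non-coding RNAs differ after sevoflurane in cells whose self-renewal was of interest. Taken as lists, genes of the antioxidant and NRF2 response and of red blood cells were higher in the sevoflurane sample. So were the unfolded protein and integrated stress response list (10 of 27 genes at least 2-fold higher) and the p53 list (9 of 18). Genes of the neuronal lineage, of microglia and of cholesterol synthesis were lower. Hmox1, which degrades haem, was higher by 4.17, and Trib3, a stress-induced pseudokinase, by 4.85. Among the lower genes, the glutamate decarboxylase gene Gad1 differed by -2.99 and the microglial complement gene C1qa by -3.46. The genes of DNA replication and of the mitochondrial respiratory chain stayed mostly within 2-fold.

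Over all measured probes, 5267 were higher and 1966 lower by at least 2-fold, so that 72.8% of these were higher. That split depends on the scaling: 2475 were higher and 3516 lower after quantile normalization (41.3% higher), 2728 and 2807 after the intensity-dependent correction (49.3% higher), and 2480 and 3367 in the deposited table (42.4% higher). The median of all measured probes lay at 0.36 under the scaling used, at -0.11 after quantile normalization, at -0.10 in the deposited table, at 0.18 after median scaling, at 0.44 after normexp and at 0.00 after the intensity-dependent correction, and each gene's value is to be read against that shift. The difference depended on level, with a median of 1.73 in the dimmest of 10 equal groups of probes by level, -0.17 in group 8 and 0.17 in the brightest. Gene lists were therefore placed only against genes of like level. The matching in 10 groups is coarse, and the trend can vary within a group. The reference gene list, for example, was at percentile 99.9 here but at 96.8 after the intensity-dependent correction.

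**Figure D1:**
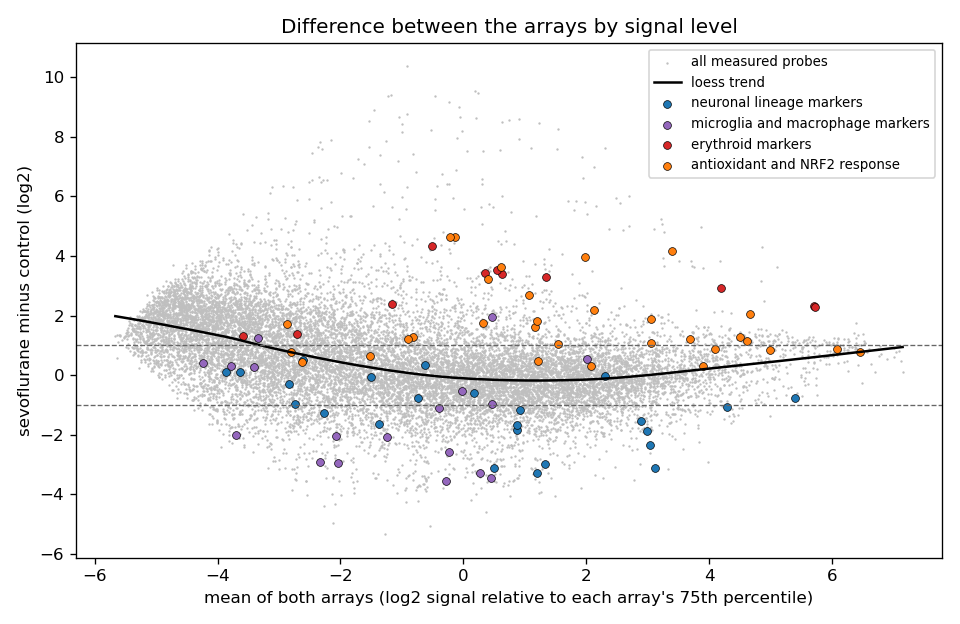
Each grey point is 1 of 16047 measured probes, with the mean of both arrays on the x axis (log2 signal relative to the 75th percentile of each array) and sevoflurane minus control on the y axis (log2). The black line is the loess trend, dashed lines mark 2-fold, and coloured points are members of 4 gene lists: erythroid genes lie above the trend and most neuronal and microglial genes below it.

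The lists share genes, so they are not independent: 5 of 18 measured p53 targets, 5 of 16 reference genes and 4 of 31 hypoxia and glycolysis genes are in another list. Random lists also leave out that genes of a list can move together. Of 31 lists that could be placed, 12 stood above genes of like level and 3 below, where chance would give 1.55. Of these 15, 12 did so in all 9 settings planned for the lists, the one used here included. The settings are not independent checks. Median scaling shifts all genes alike and cannot change a placement, and the deposited values resemble the quantile-normalized ones. The antioxidant and NRF2 list had 31 measured genes, 21 of them higher and 0 lower by at least 2-fold, with a median of 1.29 against 0.04 in random lists of like level (18 higher after the intensity-dependent correction). Srxn1, which repairs oxidised peroxiredoxins, was higher by 4.65 (signals 1651 and 125), Osgin1 by 4.65, Hmox1 by 4.17 and the quinone reductase gene Nqo1 by 3.97. In the unfolded protein and integrated stress response list, 10 of 27 genes were higher and 0 lower, with a median of 0.86. Trib3 was higher by 4.85, the transcription factor genes Cebpb and Ddit3 by 3.48 and 2.67, and Ppp1r15a, which promotes the dephosphorylation of eIF2 alpha, by 2.74. The p53 targets had 9 of 18 genes higher and 0 lower and a median of 0.93. Gdf15 was higher by 3.86 (2.18 after normexp), Perp by 2.84, Rrm2b by 2.58 and Sesn2, which is also in the integrated stress list, by 2.56. After the intensity-dependent correction the last 3 were at 1.76, 1.08 and 1.69, and Rrm2b was at 0.97 after quantile normalization. The control signals of Gdf15, Perp, Rrm2b and Sesn2 were low, at 16.6, 23.7, 13.4 and 35.3. The fixed list of heat shock genes did not stand apart, with 5 of 13 higher, a median of 0.53 and percentile 94.9 (a median of 0.30 after the correction), except after normexp, with 3 higher and percentile 98.7. The small heat shock protein genes Hspb8 and Hspb1 were higher by 2.12 and 1.15 (0.97 for Hspb1 after normexp), Cryab by 1.74 and the co-chaperone gene Bag3 by 2.28. Apoptosis genes did not either, with 6 of 23 higher, 0 lower and a median of 0.36 (3 higher, 0 lower and a median of -0.01 after the correction, 3 higher, 2 lower and a median of -0.27 after quantile normalization). Bcl2, which opposes apoptosis, was higher by 2.45 (1.08 after the correction) and Tnfrsf1a by 1.36, while Bcl2l11 was higher by 1.85 here but lower after quantile normalization and in the deposited table.

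Immediate early genes, which respond within minutes to stimulation, were higher in 14 of 22 cases and lower in 2, with a median of 1.46 (9 higher, 2 lower and a median of 0.56 after the intensity-dependent correction). Fosl1 was higher by 6.35 (3.67 after normexp), Egr3 by 3.82 (2.35 after the correction), Dusp5 by 3.76 and Ier3 by 3.07. Control signals were low for Fosl1 and Egr3, at 9.99 and 9.41, against 56.6 for Dusp5 and 516 for Ier3. Interferon response genes were higher in 12 of 16 cases and lower in 0, with a median of 1.60 (8 higher and a median of 0.96 after the correction), among them Cxcl10 by 4.39 (2.58 after normexp), Ifit3 by 3.65, Oasl by 3.08 and Ifit2 by 2.86 (1.73 and 1.81 for the last 2 after the correction). Their control signals were 21.0 for Cxcl10, 14.7 for Oasl and 24.5 for Ifit2, against 104 for Ifit3. Inflammatory cytokine and NF-kappaB target genes were higher in 10 of 15 cases and lower in 2, with a median of 1.76 (6 higher, 2 lower and a median of 0.86 after the correction), but stood apart in only 7 of the 9 settings. They share Cxcl10 with the interferon list, and Ptgs2, the inducible cyclooxygenase gene, was higher by 3.94 (1.89 after normexp), Socs3 by 3.18 (1.83 after the correction) and Nfkb2 by 2.49. Ptgs2 and Socs3 had control signals of only 11.8 and 14.3, and Nfkb2 of 51.4. Hypoxia and glycolysis genes were higher in 11 of 31 cases and lower in 2, with a median of 0.77 (5 higher, 2 lower and a median of 0.49 after the correction). Adm, the adrenomedullin gene, was higher by 3.16 and Ankrd37 by 2.05 (0.63 after the correction and 0.56 after quantile normalization), while Ndrg1 was lower, at -3.10. Pfkfb3 was higher by 1.94 here but lower after quantile normalization and in the deposited table.

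**Figure D2:**
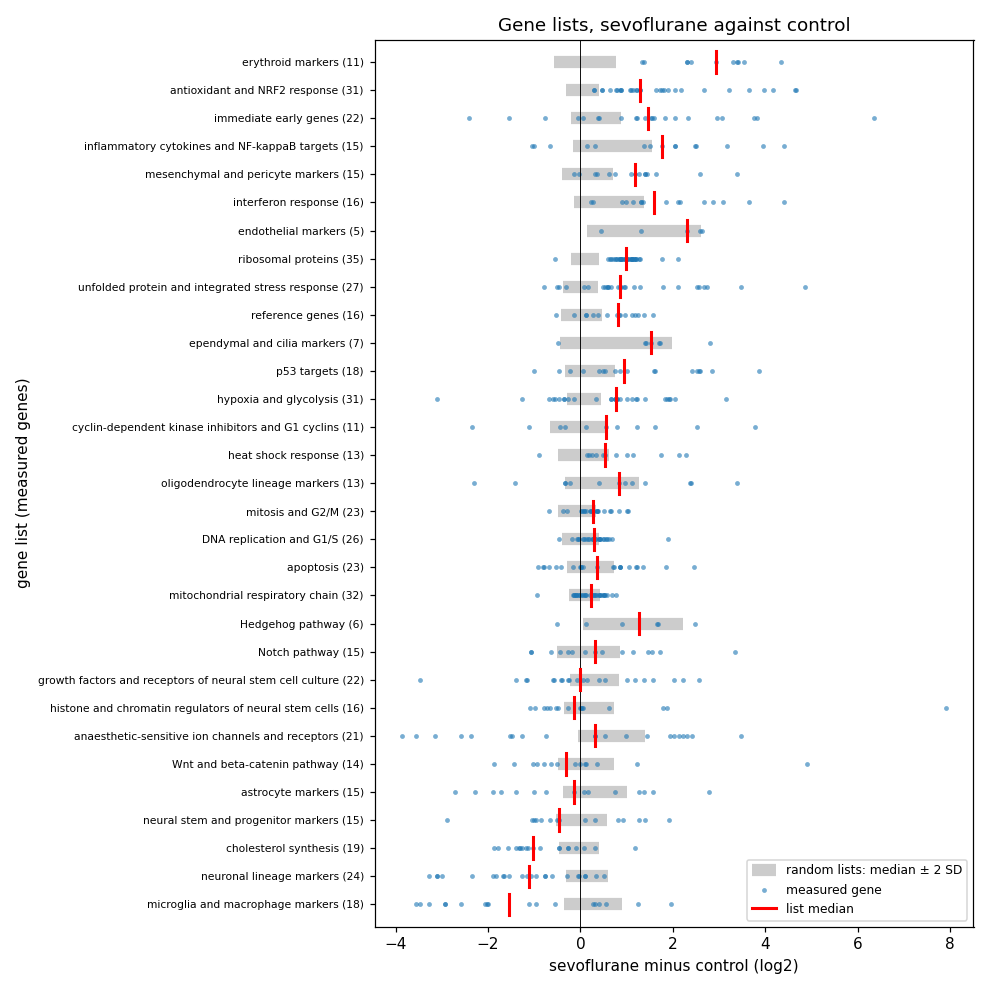
Each row is 1 of the 31 placed gene lists with its number of measured genes, and the x axis is sevoflurane minus control in log2 units. Blue points are genes, red bars are list medians and grey bars span the median ± 2 SD of random lists of like level; the erythroid median of 2.94 lies above and the microglial median of -1.56 below their grey bars. Under the intensity-dependent correction the medians of the Hedgehog, Notch, oligodendrocyte, ion channel and apoptosis lists change sign.

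Markers of other cell types moved apart. Neuronal lineage genes were lower in 13 of 24 cases and higher in 0, with a median of -1.12 against 0.14 in random lists, below all 10000 of them. The glutamate transporter gene Slc17a6 differed by -3.11 (signals 175 and 2891), the tau gene Mapt by -3.11 and Gad1 by -2.99; Tubb3, a tubulin of young neurons, differed by -0.76 (-1.29 after the intensity-dependent correction). Microglia and macrophage genes were lower in 10 of 18 cases and higher in 2, with a median of -1.56 (-0.91 after normexp), also below all 10000 random lists. Ctss differed by -3.55, C1qa by -3.46 (signals 149 and 3131), Tyrobp by -3.27 and Cd53 by -2.94 (-1.50 after normexp), whereas Aif1, the gene of the microglial protein IBA1, differed by only -0.54. All 11 measured erythroid genes were higher by at least 2-fold, with a median of 2.94 (9 of 11 after the intensity-dependent correction). They included the haemoglobin chaperone gene Ahsp at 4.34, the red cell anion exchanger gene Slc4a1 at 3.55, and Hba-a2 and Hba-a1 at 3.42 and 3.38; the globin genes are near-identical copies, so their single values are uncertain. Mesenchymal and pericyte genes were higher in 9 of 15 cases and lower in 0, with a median of 1.17 (6 higher after the correction, 5 and a median of 0.74 after quantile normalization). Rgs5 was at 3.38 and Thy1 at 2.58 (1.83 and 1.04 after the correction, and 0.90 for Thy1 after quantile normalization). Anpep was at 1.64 and Prrx1 at 1.44. Astrocyte genes did not stand apart, with 4 of 15 higher, 6 lower and a median of -0.13, but did so below after the correction, with a median of -1.09, 2 higher and 8 lower, and in 3 further scalings. Apoe differed by -2.71, Sparcl1 by -1.89, Gjb6 by 2.78 (1.29 after the correction), and Gfap, the astrocyte filament gene, by -0.75 (-1.43 after the correction, -0.24 after normexp). Oligodendrocyte lineage genes were higher in 5 and lower in 2 of 13 cases (3 and 2 after the correction, 2 and 4 after quantile normalization). Bcas1 was at 3.39, Gpr17 at 2.39 (0.84 after the correction), Cspg4 at 2.37 and Ugt8 at -2.29 (-1.10 after normexp). Endothelial genes (4 of 5 higher, 1 after the correction) and ependymal and cilia genes (6 of 7 higher, 2 after the correction) were within the range of random lists; Cldn5 was at 2.63, Flt1 at 2.59, Tmem212 at 2.81 and Rsph4a at 1.73, and after the correction these 4 were at 1.47, 0.86, 1.58 and 0.80.

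Neural stem and progenitor markers had 3 of 15 genes higher and 3 lower, with a median of -0.46 at percentile 3.38. The receptor phosphatase gene Ptprz1 differed by -2.90, Msi1 by 1.40 (0.51 after the correction), the filament gene Nes by 1.27, the stem cell factor gene Sox2 by -0.85 and the Notch effector gene Hes1 by 0.11, negative in 1 of 6 scalings. Notch pathway genes were higher in 5 and lower in 2 of 15 cases (3 and 3 after quantile normalization), with Numbl at 3.35, Notch3 at 1.71, Heyl at 1.55 (0.70 after the correction) and Lfng at 1.46. Wnt pathway genes were higher in 2 and lower in 3 of 14 cases (1 and 5 after quantile normalization). Lef1 was at 4.91 and the receptor genes Fzd9 and Fzd1 at -1.86 and -1.44 (-2.85 and -1.32 after the correction, and only -0.42 for Fzd9 after normexp). Wnt7b was at 1.23 here but negative after quantile normalization, after the intensity-dependent correction and in the deposited table. Of 6 Hedgehog genes 3 were higher (0 after the intensity-dependent correction). Smo was at 2.48 and Sufu at 1.66 (0.87 and 0.72 after the correction), and Cdon at 1.67 and Gli2 at 0.89, both negative in 3 of 6 scalings. Growth factor and receptor genes were higher in 7 and lower in 4 of 22 cases (3 and 5 after the intensity-dependent correction). The neurotrophin receptor gene Ntrk3 differed by -3.48, Fgf1 by 2.56, Lifr by 2.21 (0.78 after the correction) and Spry4 by 2.02, and Bdnf by 1.18, negative in 3 of 6 scalings. Mki67, Dcx and Olig2 had no probe matched through an accession. Chromatin regulators had 3 of 16 genes higher and 1 lower (1 and 2 after the correction). Hmga1 was at 7.91, Ezh1 at -1.08 (-0.88 after normexp), and Rest at 1.78 here but negative after quantile normalization and in the deposited table.

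DNA replication genes were higher in 1 of 26 cases and lower in 0 (0 and 1 after the intensity-dependent correction), with a median of 0.29 at percentile 93.1. Gins2 was higher by 1.90 (0.35 after the correction), Mcm10 by 0.68, Orc1 by 0.62 (0.29), Rfc4 by 0.57, and the replication clamp gene Pcna by 0.13, with the opposite sign in the other 5 scalings. Mitosis genes were higher in 2 of 23 cases and lower in 0, with a median of 0.27 at percentile 95.1; the kinase gene Aurkb was at 1.03 and Ube2c at 1.01 (0.98 and 0.92 after normexp), Bub1 at 0.84 and Prc1 at -0.68. Cyclin-dependent kinase inhibitors and G1 cyclins were higher in 4 and lower in 2 of 11 cases, with a median of 0.56, and stood apart in 8 of the 9 settings. The inhibitor genes Cdkn2b and Cdkn1a were higher by 3.77 and 2.53 (Cdkn1a signals 6079 and 2010), Ccnd2 by 1.61, and Mycn differed by -2.35. Cholesterol synthesis genes were lower in 10 of 19 cases and higher in 1, with a median of -1.02, below all 10000 random lists. Dhcr7 and Sqle, which encode enzymes of that pathway, differed by -1.87 and -1.56, and Tm7sf2 by -1.39. Of 32 respiratory chain genes 0 were higher or lower by at least 2-fold (0 and 1 after the correction), with Ndufs4 at -0.95, Ndufa2 at 0.76, Cox7b at 0.67 and Sdhb at 0.57. Ribosomal protein genes were higher in 17 of 35 cases and lower in 0, with a median of 0.98, but in only 1 case after the correction, with a median of 0.35. Rpl10 was higher by 2.10, and Rpl6 by 1.76, Rps23 by 1.29 and Rpl35 by 1.28 (0.99, 0.69 and 0.75 after the correction). Commonly used reference genes were higher in 5 of 16 cases (3 after the correction), with a median of 0.81 (0.34 after the correction), and stood apart in 6 of the 9 settings. Gusb was at 1.57, B2m at 1.24 and Actb at 1.19 (0.81 after the correction). Ion channels and receptors on which anaesthetics act were higher in 8 and lower in 8 of 21 cases (3 and 8 after the correction, 3 and 10 after quantile normalization, where the list stood apart below in both cases). Gabra5, a subunit of the GABA receptor, differed by -3.87, the glycine receptor gene Glra2 by -3.56, and the glutamate receptor genes Gria4 and Grin2b by -3.15 and 3.46. After normexp these 4 were at -1.71, -2.31, -1.36 and 2.18, and the list was within the range of random lists. Members against the direction of their list were named after their values were seen. Tmem119 was at 1.95 and Laptm5 at 1.24 (0.22 after the correction) among microglial genes, and Nr4a3 at -2.42 and Ier5 at -1.55 among immediate early genes. Pfkp was at -1.25 beside Ndrg1 among hypoxia and glycolysis genes, and Vcam1 at -1.05 and Cx3cl1 at -1.01 (-0.84 and -0.94 after normexp) among inflammatory genes. Rbl2 was at -1.10 (-0.69 after normexp) beside Mycn, and Ebp at 1.18 among cholesterol synthesis genes. The stem cell genes Pax6 and Lhx2, at -1.01 and -1.06 (-0.88 and -0.94 after the correction), were named in the same way.

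Among the 10 lowest single genes of the brighter part, the membrane protein gene Cd200 differed by -4.59 (signals 95.8 and 4397), Ptpro by -4.19, Cdh13 by -3.94 and the axonal adhesion gene L1cam by -3.93. Cttnbp2 differed by -3.71, the neurexin gene Nrxn3 and the dynein gene Dync1i1 both by -3.61, Spock2 by -3.59 and the neuronal factor gene Myt1l by -3.58. The 10 highest included Pcdhb2 at 9.54 (signals 11278 and 28.8), Mas1l at 9.17, the sperm protamine gene Prm2 at 8.99, Vangl1 at 8.57, Zzz3 at 8.49, Bccip at 8.19, Hmga1 at 7.91, Chm at 7.63 and the muscle creatine kinase gene Ckm at 7.53. All 20 kept their sign in all 6 scalings, but the scalings moved these values by far less than a change of sign needs. The kept sign is therefore no check of them. Each also rests on only 1 usable control spot, so agreement between spots could not be examined. As a measured fact beside them, 1 of the 10 control sequences from the viral E1A gene, which the rat lacks, was also higher by at least 8.29 on the sevoflurane array, a lower bound because its control signal was not well above background. Of 240 genes with at least 2 measured probes, 117 had a probe at least 2-fold apart, in 66 all probes were so in 1 direction, and in 5 (Bcl2l1, Cacna2d1, Kcnk2, Pfkfb2 and Thra, named after their values were seen) probes were so in opposite directions. The SD between probes of a gene had a median of 0.11 and a 95th percentile of 1.60.

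Of genes above background only on the sevoflurane array, 2138 in number, the olfactory receptor gene Or52e8b was at least 636-fold higher, Gzmfl1 at least 501-fold and the potassium channel gene Kcnj9 at least 391-fold. Of 199 genes above background only on the control array, Bcl2a1 was at least 24.7-fold lower in the sevoflurane sample and the macrophage mannose receptor gene Mrc1 at least 15.0-fold. For 70 of these 199 the bound lay under 1 and no fold is given. Of the 4491 probes seen only on the sevoflurane array, 73.1% had a signal at or below 24.4, the level of the second brightest E1A sequence there.

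In the non-coding section 4987 of 9294 usable probes were measured (53.7%), against 11042 of 15293 RefSeq mRNA probes (72.2%). At least 2-fold higher were 43.5% of the non-coding and 28.0% of the mRNA probes, and lower 13.0% and 11.9%. With mRNA probes weighted to the levels of the non-coding ones, 36.8% were higher and 10.2% lower. After the intensity-dependent correction, 21.7% of non-coding probes were higher and 20.2% lower, against 16.1% and 17.6% of level-matched mRNA probes. The highest non-coding probes of the brighter part were BC088211 at 10.37, uc.243+ at 9.48, XR_008202 at 8.78, EF673689 at 8.67 and AB190509 at 8.66. The lowest were XR_008801 at -5.07, MRAK013810 at -4.25, MRAK036014 at -4.22, AY539885 at -4.05 and MRBC030402 at -4.00. Among 35 well-known long non-coding RNAs only 4 had a probe matched through an accession. All 4 were measured, too few for placement, and nothing can be said of the others. The RNase P RNA Rpph1 was higher by 2.71 and the telomerase RNA Terc by 2.45 (1.14 after the correction). Gas5, a host of small nucleolar RNAs, was higher by 1.89, and the imprinted H19 by 0.49.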

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

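All tests in this part were chosen after the results were seen. Control spots enter no comparison above, but of 10 sequences of the viral E1A gene, each on 32 spots, 5 were well above background on the sevoflurane array and 0 on the control array. Their median processed signal over sequences was 12.6 on the sevoflurane array and 1.84 on the control array. The sequence named E1A_r60_a107 had 1187 on the sevoflurane array and 4.18 on the control array.

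The first pattern is that dim probes were brighter on the sevoflurane array. The single scaling factor per array cannot be its whole cause, because the median difference spanned 1.91 log2 units over 10 equal groups of probes by level, and a single factor moves all groups alike. Signal that does not come from the probes' own transcripts is a candidate explanation that stays open: 5 of the 10 E1A sequences were higher by at least 1 log2 unit as a lower bound, and the other 5 were not well above background on either array, so no fold is given for them. Olfactory receptor genes, whose expression is not typical of neural stem cells, went the same way, with 66.5% of 1156 probes above background on the sevoflurane array and 15.3% on the control array. The 153 negative control spots, however, had a median processed signal of 2.33 on the sevoflurane array and 1.79 on the control array. Their median thus showed no rise of the size seen for the brighter E1A sequences. Whether E1A RNA had been added to the samples was not examined. An induction of weakly transcribed genes by sevoflurane, in addition to signal of other origin, was not tested and stays open.

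The second pattern is that 175 probes were higher by at least 64-fold and 0 were lower by as much, where 72 of the 175 were well above background on both arrays, and of the 103 others, with a control signal not well above background, 51 were higher by that much even as a lower bound. A local spot defect is argued against for the 76 of them with several spots, whose spots on the sevoflurane array had a median SD of 0.11 and a highest SD of 0.38. For the 99 with a single spot, this cannot be decided. Signal from other labelled material may account for some, since 1 E1A sequence was higher by at least 8.29. Olfactory receptors made up 13 of 80 such named mRNA probes (16.2%) against 8.11% of all 14248. That comparison cannot decide the cause, because it was not matched on the control signal. Only 15.3% of olfactory probes were above background on the control array, and dim probes there have the most room for such a rise. Kiaa0040 was the only such gene with a second probe, and its probes were at 6.55 and 6.65, so a rise of its transcript stays open as an untested effect of sevoflurane.

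The third pattern is that markers of neurons and microglia were lower while those of mesenchymal and erythroid cells were higher. A lower share of neural stem cells, with the other types unchanged relative to each other, would raise all other types alike. The gap of 4.68 log2 units between the erythroid and microglial medians, each taken against genes of like level, argues against that form only. This gap restates the pattern and was known beforehand, so a lower share beside other changes is not decided. Stem and progenitor markers themselves had a median of -0.46 at percentile 3.38, with 3 of 15 higher and 3 lower. Fewer neurons and microglia in the sevoflurane culture may account for the lower lists, of which 0 measured genes are in another list, but the 9 microglial genes with a control signal of at least 500 differed unequally, with an SD of 1.45: Ctss (1938 in the control) was at -3.55 and Aif1 (826) at -0.54. That spread does not settle it, because signal of the E1A kind could mask part of a loss. Scan day, handling of the culture and sevoflurane cannot be told apart, with 1 array per scan day.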

How the results depend on the processing

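The minimum signal from the E1A sequences and detection by a positive and significant signal were chosen after seeing the data. That minimum, called the E1A level below, was 24.4, the signal of the second brightest E1A sequence on the sevoflurane array. The brightest had 1187, so probes above the minimum are not clear of signal of that kind. The count of probes at least 2-fold higher, 5267, became 2475 after quantile normalization, 2728 after the intensity-dependent correction, 2480 in the deposited table, 1161 in the brighter part of the probes, 13274 with no filter, 3355 at 3-fold and 3172 with both signals above the E1A level. The count lower, 1966, became 3516 after quantile normalization, 3367 in the deposited table, 3330 at 1.5-fold and 874 at 3-fold. The changes at other size rules follow from their construction. Fewer or more probes change the counts by construction. In the brighter part, with 1161 higher and 1328 lower, the split changed too. A filter on level changes the split through the trend on level. The median difference was 1.73 in the dimmest of 10 groups and -0.17 in group 8. The cause of that trend and of the other changes was not tested. Probes seen only on the control array, 396, became 103 by positive and significant signal and 156 above the E1A level, and those seen only on the sevoflurane array, 4491, became 1210 above it. The gap between the non-coding and the level-matched mRNA share of higher probes, 6.60 percentage points, was 5.22 after quantile normalization and between 5.39 and 7.03 otherwise. Lists below genes of like level numbered 5 instead of 3 after quantile normalization, after the intensity-dependent correction and in the deposited table, and lists above numbered between 11 and 13 in all settings. No list that stood apart changed side of the random median. Of 164 named probes, 146 were at least 2-fold apart and 6 of these changed sign. After quantile normalization, after the intensity-dependent correction and in the deposited table respectively, Wnt7b was at -1.50, -0.64 and -1.002, Cdon at -0.82, -0.16 and -0.72, and Bdnf at -0.43, -0.25 and -0.43. After quantile normalization and in the deposited table, Bcl2l11 was at -0.37 and -0.37, Pfkfb3 at -0.34 and -0.33, and Rest at -0.27 and -0.26. All 6 were dim on both arrays, and signal over background limits what can be said of such genes. Leaving out saturated probes removed nothing, because no spot was saturated. No paired analysis was possible because there is 1 array per group and no test.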

Other observations

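The gene families in this part were chosen after seeing the data, by placing all 147 symbol stems with at least 10 measured genes among random lists of like level. Above stood 15 and below 15, where chance would give 7.35, and 19 did so in all 6 scalings. The scalings are not independent checks, since median scaling cannot change a placement. Among the families below were the gamma protocadherins, adhesion proteins of neurons, of which 13 of 14 were lower by at least 2-fold with a median of -1.63 (13 lower after the intensity-dependent correction, but 0 lower and a median of -0.61 after normexp). Pcdhga3 differed by -1.87 and Pcdhga7 by -1.73, while Pcdhgc5 was higher by 2.07 (0.41 after the correction); these genes share sequence, so their values are not independent, and the median after the correction was -2.36. Genes of the Gri stem, which are ionotropic glutamate receptors and their partners Grip1 and Grip2, were lower in 5 and higher in 2 of 16 cases with a median of -0.33 (12 and 2 after the correction, 3 and 2 with a median of 0.36 after normexp). Gria4 was at -3.15 and Gria2 at -2.58, and Grin2b at 3.46 and Grin2c at 2.22. Potassium channel genes were lower in 14 and higher in 12 of 41 cases with a median of -0.35 (20 and 4 after the correction), but lower in 8 and higher in 11 with a median of 0.40 after normexp. Kcnn2 was at -2.76, and Kcnt2 at 2.56, Kcnv1 at 2.55 and Kcnn3 at 2.49 (1.46, 2.05 and 0.86 for the last 3 after the correction). Zinc finger genes of the Zfp series were lower in 26 and higher in 13 of 139 cases (34 and 3 after the correction, 15 and 9 after normexp), with Zfp93 at -2.04 and Zfp36 at 2.32.

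Above genes of like level stood the glutathione S-transferases, which attach glutathione to reactive compounds, with 13 of 15 genes higher and 0 lower (9 and 1 after the correction); Gsta1 was higher by 4.39 and Gsta3 by 4.36. Annexins were higher in 8 of 10 cases (6 after the correction), with Anxa3 at 3.21 and Anxa4 at 2.21, and serpins in 11 of 14 (8 after the correction, 5 after quantile normalization), with Serpinb9 at 3.13. The 1 lower serpin was Serpini1, a serpin of neurons, with signals of 141 on the sevoflurane array and 2153 on the control array. Genes of the Hsp stem, some of them also in the fixed heat shock list, were higher in 7 and lower in 1 of 20 cases, with a median of 0.60 at percentile 99.1. They stood apart in 4 of the 6 scalings, but not after the correction (median 0.36, percentile 97.2) or in the deposited table (0.32, percentile 97.0). Mitochondrial ribosomal protein genes had a median of 0.46 with 5 of 55 higher and 0 lower (6 and 1 after the correction, 2 and 3 after quantile normalization). Families of other tissues also stood above: keratins were higher in 17 of 17 cases (11 after the correction), with Krt80 at 5.25, defensins in 15 of 16 (10), vomeronasal receptors in 21 of 22 (7) and olfactory receptors in 170 of 173 (81).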
